A study of Homo sapiens with 3 samples.

How the data were processed

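Total RNA of 3 human cell lines was profiled on 3 Affymetrix expression arrays, 1 array per line. The lines all derive from HT1080, an established human fibrosarcoma line. Per the labels' protocols, Zeo was mock-transfected, RECK was stably transfected with a vector for RECK, and RECK/4NQ with the same vector for a form of RECK in which 4 asparagines that carry N-linked glycans were replaced by glutamine. Cells were grown with 10% fetal calf serum and 50 µg/mL Zeocin, the selection drug, and biotin-labelled cRNA was made from 8.1 to 15 µg of RNA, per the labels' protocols. The labels do not say whether a line is a single clone or a pool of transfected cells.

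The deposited values are MAS5 signals, an intensity on a linear scale with 1 value per probe set and array; MAS5 is named in the submitters' processing notes, and its version and scaling target are not given in the sources used here. MAS5 summarises perfect-match probes after subtracting an estimate from mismatch probes, so weak signals are noisy and low values have large ratios by chance. Each array held 54675 probe sets. The sum of signals was 12517000 on the Zeo array, 11372200 on the RECK array and 12349800 on the RECK/4NQ array, and the median signal was 20.3, 17.8 and 17.3. The mean after removing the lowest and highest 2% was 111, 98.5 and 106 on these arrays, so the deposited values were not at 1 common trimmed mean. No genome build is named for the arrays, and no coordinates are given.

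All calculations were made here from these intensities, as deposited and without further scaling. Of the probe sets, 62 were control probe sets and left out of gene results, 41091 had 1 gene symbol in the platform's annotation, 1801 had several and 11721 were not listed there with a gene. Only probe sets with 1 symbol named a gene. Through the RefSeq gene table for GRCh38, 41043 of them matched a current gene and 0 symbols needed an update. This table served only for names and for which genes neighbour each other. A gene was represented by its brightest probe set, the one with the highest mean log2 signal over the 3 arrays, which gave 19775 genes.

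Signals below a floor of 12.2, the 40th percentile of all values, were set to the floor before log2 ratios were taken. A gene was counted as higher or lower if its signals differed at least 2-fold with both arrays at or above the floor, or if 1 array was below the floor and the other at least 2 times the floor. In the second case the fold is a lower bound and is given as "at least". With 1 array per group there is no test, no p-value and no SD. As an error scale, each ratio was set against the robust spread (1.4826 times the median absolute deviation) of the ratios of the 1000 genes nearest in level, which holds real differences as well as noise. A gene stood apart on 1 array if it was at or above the floor on all 3 arrays, differed at least 2-fold in 1 direction from both other arrays, and those differed less than 1.5-fold from each other.

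Before the data were examined, 42 gene lists (pathways, protein families and markers of other cell types) were fixed. For each list and comparison the median log2 ratio of members with a mean level at or above the floor was taken, minus the median of all 14289 such genes. It is given with its percentile among 10000 random lists of the same size drawn from the same 20 bins of level. These percentiles describe the arrays and do not test the conditions. The percentile is matched on level and the relative median is not, so the latter's size and sign can include a shift that goes with level. For RECK/4NQ over Zeo, housekeeping genes had a relative median of 0.13 at percentile 52.21, and ribosomal proteins 0.10 at percentile 17.75. Of the 126 percentiles, 31 lay outside 2.5 to 97.5, where 6.3 are due by chance, and 13 lay outside 0.5 to 99.5, where 1.26 are due. In data simulated with no effect, 7.14% of 126 percentiles lay outside 2.5 to 97.5.

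The genes named in the text were set by a rule fixed before the data were examined. Per comparison it took the 10 highest and 10 lowest ratios among genes measured on both arrays, with a mean level at or above the 60th percentile of all signals, a difference of at least 2-fold and no other measured probe set moving the opposite way. It added up to 5 genes per direction with 1 array below the floor, the brightest on the other array, and 5 per direction for each array that stood apart. RECK, MMP2, MMP9, MMP14 and TIMP1 to TIMP3 were always included, with 2 to 4 members of each described list with the largest ratios. Some genes that the rule took are not reported here. A list's counts of higher and lower members cover all members with a probe set, and its median those at or above the floor.

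The calls were tested on simulated data with the real genes' levels and level-dependent noise. For the comparison of RECK with Zeo over 19775 genes, 83.9% of genes changed 2.83-fold were recovered, 98.5% at 4-fold and 99.7% at 8-fold, while 1043 unchanged genes were also called, against 2124 calls in the data. This noise was taken from the spread of RECK over RECK/4NQ in the data and so holds real differences. That spread was wider than for RECK over Zeo, at 0.61 against 0.52 for signals of 27.8 to 95.5. The simulated calls are therefore not matched to the noise of RECK over Zeo. Genes below the floor were simulated at the floor, so overlaps and genes standing apart were compared with simulated data over 10802 genes with a mean level at or above the 60th percentile.

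Alternatives were quantile normalisation, centring all arrays on a common median, floors at the 20th and 60th percentile, the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at (those that can match several transcripts or genes), and a 3-fold threshold. The mean of probe sets was taken before the floor was applied, so signals below the floor enter these means as measured. A floor at the 80th percentile and the subtraction of the median of neighbouring genes were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.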

Results

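RNA from 3 HT1080 fibrosarcoma lines was measured: mock-transfected cells (Zeo), cells transfected with RECK and labelled as overexpressing it (RECK), and cells transfected with RECK/4NQ, a form of RECK that lacks 4 N-glycosylation sites. RECK is a membrane-anchored glycoprotein known as an inhibitor of matrix metalloproteinases and a suppressor of tumour invasion. The comparisons ask which transcripts differ in the line transfected with RECK, and which of these differ when its glycosylation sites are lost. There are no replicates, so each value below compares 1 array with another, and differences between the lines other than the transfected gene cannot be separated from it.

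The 3' to 5' signal ratio, a measure of RNA integrity, of GAPDH was 0.961 on the Zeo array, 0.979 on the RECK array and 0.923 on the RECK/4NQ array, and that of ACTB was 1.32, 1.28 and 1.36. Across 12411 genes measured on all arrays, log2 signals correlated at 0.964 between RECK and Zeo, 0.971 between RECK/4NQ and Zeo, and 0.962 between RECK and RECK/4NQ, where genes are not independent replicates. The hybridisation control transcripts were 1.30-fold brighter on the RECK array than on the Zeo array (mean log2 ratio 0.38 ± 0.18, SD over 9 probe sets) and 0.37 ± 0.15 above those on the RECK/4NQ array, while RECK/4NQ over Zeo was 0.0092 ± 0.097. The labelling controls were dimmer than on the Zeo array, by a mean log2 ratio of -0.29 ± 0.14 on the RECK array and -0.34 ± 0.12 on the RECK/4NQ array (SD over 12 probe sets). The median log2 ratio of all genes was -0.20 for RECK over Zeo, -0.12 for RECK/4NQ over Zeo and -0.06 for RECK over RECK/4NQ. Ratios of single genes are given as deposited, and medians of gene lists relative to these shifts.

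RECK itself was measured by 5 probe sets. The brightest had a signal of 264 on the Zeo array, 387 on the RECK array and 442 on the RECK/4NQ array, which is 1.47-fold and 1.68-fold above Zeo. The other 4 were below 27 on every array, and of these 216156_at was at 26.2 in Zeo, 2.08 in RECK and 11.3 in RECK/4NQ. Averaging the probe sets gave log2 ratios of -0.16 for RECK and 0.34 for RECK/4NQ over Zeo, and leaving out shared probe sets gave -0.047 and -0.13. The averages were taken before the floor was applied, so the signal of 2.08 of 216156_at enters the first as measured. Whether any of these probe sets lies in the transfected sequence is not known here, so these signals do not check the labels.

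In the RECK line, the gelatinase MMP9 was 9.60-fold lower than in Zeo, with a signal of 203 against 1947. Transcripts of the cytokine IL1B were 6.09-fold lower (260 against 1583), and a second IL1B probe set read 342 against 1238. Genes known as targets of p53 and of TGF-beta signalling were higher as groups. The largest ratio of a gene measured on both arrays was that of BEX1, an X-linked gene best known in the nervous system, with a signal of 2469 against 80.6.

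Among the 10 largest ratios above Zeo, BEX1 was 30.6-fold higher, SULF2, an extracellular heparan sulfate sulfatase, was 25.1-fold higher (714 against 28.4), and SUGCT, a mitochondrial CoA transferase, was also 25.1-fold higher (628 against 25.0). The membrane transporter SLC43A3 was 21.7-fold higher, the long noncoding RNA SNHG18 20.3-fold, C16orf54 13.5-fold, and the transcription factor SOX7 10.7-fold. BAMBI, a decoy receptor of the TGF-beta family, was 10.3-fold higher (428 against 41.7), the neurofilament gene NEFL 9.94-fold (675 against 68.0) and JMJD8 9.91-fold. These 10 ratios lay between 6.59 and 12.5 spreads above the median of all genes. HSD17B2, a steroid dehydrogenase, was below the floor in Zeo and at 259 in RECK, at least 21.2-fold higher. SPINK1, a secreted trypsin inhibitor, was at least 10.5-fold higher.

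Among the 10 lowest ratios, NMRAL1, an NADPH-binding sensor protein, was 12.6-fold lower (79.1 against 994), TMEM132D 12.2-fold lower, and MYH10, the heavy chain of nonmuscle myosin IIB, 11.2-fold lower (24.8 against 278). MTMR1, a phosphoinositide phosphatase, was 8.36-fold lower, the potassium channel subunit KCNAB2 7.96-fold, the dynein gene DNAH6 7.63-fold by its brightest probe set (another, dim, went from 2.13 to 17.4), the proteoglycan gene CSPG4 6.54-fold and the semaphorin SEMA6B 6.46-fold. The Notch ligand DLL1 was 8.03-fold lower by its brightest probe set, while a dimmer one went from 2.97 to 30.8 and the mean of both gave a log2 ratio of 0.19. The signal of 2.97 lies below the floor, which was not applied before averaging. ARMCX2 was at least 20.5-fold lower, the cancer-testis antigen GAGE1 at least 8.18-fold, and the secreted protein SERPINF1 at least 7.56-fold. Averaging all probe sets gave log2 ratios of -2.18 for KCNAB2, -1.63 for SEMA6B, 2.16 for NEFL and 3.58 for SULF2, which were smaller than with the brightest probe set.

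Of the listed p53 targets 17 had a probe set, of which 4 were at least 2-fold higher in RECK, 0 were lower and 13 were not past 2-fold. Their median log2 ratio relative to all genes was 0.73, at percentile 100 of the random lists, and 16 of the 17 were above the median of all genes. The stress cytokine GDF15 had a signal of 7199 against 2692, the kinases PLK2 and PLK3 were at 256 against 113 and 322 against 136, and the cell cycle inhibitor CDKN1A was at 3138 against 2170. FAS was lower by its brightest probe set, at 46.5 against 62.4. MDM2 was at 92.05 against 68.55 by its brightest probe set, while another read 29.2 against 92. Of 15 TGF-beta targets, 4 were higher, 0 lower and 11 not past 2-fold, with a relative median of 0.65 at percentile 100. Besides BAMBI these were the matrix protein gene TGFBI, at 7127 against 1649, PMEPA1, at 1151 against 378, and INHBA, at 46.3 against 22.7. The median of the TGF-beta list was 0.46 after the median of neighbouring genes was subtracted. For RECK/4NQ over Zeo this list had a relative median of 0.27 at percentile 97.34, with 1 higher, 1 lower and 13 not past 2-fold. PMEPA1 was at 888 in RECK/4NQ.

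Focal adhesion and cytoskeletal genes had 3 of 19 members higher, 1 lower and 15 not past 2-fold, with a relative median of 0.44 at percentile 99.99. TAGLN, a smooth muscle actin-binding protein, had a signal of 367 against 111, the myosin light chain gene MYL9 one of 2636 against 1125, and ACTA2, smooth muscle actin, one of 1184 against 590. A list for the epithelial-mesenchymal transition, which mixes its regulators with epithelial and mesenchymal markers, had a relative median of 0.34 at percentile 98.98. None of 16 members was past 2-fold, and the mix gives this median no direction for the transition.

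Cytokines and NF-kB targets had 5 of 26 members lower, 1 higher and 20 not past 2-fold, with a relative median of -0.27 at percentile 2.45 (-0.47 without shared probe sets and -0.16 with neighbour medians subtracted). Besides IL1B, the chemokine CCL5 was at 18.6 against 69.6 and the NF-kB subunit RELB at 140 against 283. Of 14 cholesterol synthesis genes none passed 2-fold, and their relative median was -0.32 at percentile 0.76 (-0.19 without shared probe sets). STARD4, INSIG1 and DHCR7 had 1.77-fold, 1.58-fold and 1.51-fold lower signals. Of 29 genes of the unfolded protein response, 1 was higher, 1 lower and 27 not past 2-fold, with a relative median of -0.21 at percentile 1.74 that came to -0.09 without shared probe sets. Here ASNS, asparagine synthetase, was 3.65-fold lower, and the transcription factor ATF3 was 2.77-fold higher by its brightest probe set, while its others read 140 against 137 and 49.6 against 53.1. Feedback regulators of ERK signalling included the phosphatase DUSP5 at 300 against 1291 and SPRY4 at 134 against 381, and the ERK-responsive factor ETV4 was at 266 against 711. That list, with 3 of 19 members lower, 0 higher and 16 not past 2-fold, had a relative median of -0.19 at percentile 3.97. In RECK/4NQ, DUSP5 was at 565, SPRY4 at 297 and ETV4 at 673, and ASNS was at 302 against 639 in Zeo.

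Among the proteins RECK is known to act on and their inhibitors, MMP2 had a signal of 2429 in RECK against 1307 in Zeo, with neighbouring genes at a median of 0.32 in log2 ratio. MMP14, which activates MMP2 at the cell surface, had a signal of 895 against 1248. TIMP1, a secreted metalloproteinase inhibitor, was at 4921 against 9692, TIMP2 at 2805 against 2561 and TIMP3 at 200 against 60.3. Relative to all genes these log2 ratios were 1.09 for MMP2, -0.29 for MMP14, -0.78 for TIMP1, 0.33 for TIMP2 and 1.92 for TIMP3. The TIMP3 log2 ratio of 1.73 as deposited was 2.35 with probe sets averaged. In RECK/4NQ, MMP2 was at 1692, MMP14 at 1199, TIMP1 at 9116, TIMP2 at 1912 and TIMP3 at 78.0. The list of RECK and its partners had 1 of 14 members higher in RECK than in Zeo, 2 lower and 11 not past 2-fold. Its relative median was -0.07 at percentile 31.68, and 0.10 at percentile 66.43 for RECK/4NQ over Zeo. Of 18 metalloproteinase genes 1 was higher in RECK than in Zeo, 3 were lower and 14 were not past 2-fold, with a relative median of 0.06 at percentile 67.07. MMP15 was at 83.0 against 12.7 and MMP25 at 20.5 against 75.7. The lysosomal protease CTSB was at 3080 against 1134.

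In all, 797 genes were higher in RECK than in Zeo and 1327 lower, of 19775. Both signals were at or above the floor for 436 and 796 of these, and 200 and 93 also lay over 3 spreads from the median of all genes. Other probe sets of the called genes moved in the same direction in 70.1% of 613 cases, and in 83.0% of 259 cases for genes with a mean level above the 80th percentile. They also reached 2-fold in 22.5% and 35.9%. The share due by chance was not computed. It may exceed 50%, since most called genes were lower and the median ratio of all genes was below Zeo. Dimmer probe sets moved the opposite way in ACTA2 and GDF15. The share of higher genes among all called was 37.5% as deposited, 53.8% after quantile normalisation (1068 higher, 917 lower) and 54.8% after median centring (1106 higher, 911 lower).

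In the RECK/4NQ line, MMP9 and IL1B were not lower than in Zeo: MMP9 had a signal of 2306 against 1947 and IL1B one of 2343 against 1583. Among genes with no opposing probe set, the largest decrease was in UCA1, a long noncoding RNA known from bladder cancer, which was 10.9-fold lower at 146 against 1597. FGD2, singled out after its values were seen, was lower still by its brightest probe set, at 23.4 against 416, but another of its probe sets moved the opposite way. Matrix and integrin genes were lower as groups.

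High ratios to Zeo belonged to PTGES, a prostaglandin E synthase, 7.20-fold higher (346 against 48.0) with neighbouring genes at a median of -0.41 in log2 ratio, and to SBSN, an epidermal secreted protein, 6.13-fold higher (2543 against 415). NEFL was 5.88-fold higher, SNHG18 4.28-fold and C16orf54 4.56-fold. MSRB2, a methionine sulfoxide reductase, was 5.77-fold higher by its brightest probe set, with its others below the floor. The cadherin gene CDH11 was 5.60-fold higher by its brightest probe set, of a kind that can match several transcripts. A second such probe set went from 10.8 to 47.3, and another was lower, with a bound of -1.70 on its log2 ratio set by the floor. The adenylate kinase gene AK5 was 4.59-fold higher, and the mean of its probe sets gave -0.37. That mean includes a signal of 3.08 in RECK/4NQ, below the floor, which was not applied before averaging. ACTL8, an actin-like gene, was at least 15.3-fold higher, the channel gene TRPM4 at least 6.72-fold and the transcriptional repressor GFI1 at least 6.45-fold.

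Among low ratios, the G protein subunit GNGT2 was 7.93-fold lower (19.5 against 155), C19orf33 6.84-fold (85.6 against 586) and PAEP, the secreted glycoprotein glycodelin, 6.51-fold (87.2 against 568). Genes next to PAEP had a median log2 ratio of -0.58. The helicase RECQL was 5.71-fold lower, the proton channel HVCN1 5.43-fold and EPOP 5.34-fold. The homeobox gene MNX1 was at least 6.19-fold lower. With probe sets averaged, log2 ratios were 1.73 for PTGES and 1.96 for NEFL.

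Of 40 extracellular matrix genes, 8 were lower, 1 was higher and 31 were not past 2-fold, with a relative median of -0.25 at percentile 0.03 that came to -0.12 when probe sets were averaged, -0.15 after quantile normalisation and -0.059 with the floor at the 80th percentile. Tenascin, TNC, had a signal of 82.1 against 436, the collagen gene COL5A1 one of 92.0 against 201 and the crosslinking enzyme LOX one of 170 against 453, while THBS2 had 168 against 69.5. Integrin and adhesion genes had 7 of 31 members lower, 2 higher and 22 not past 2-fold (-0.23, percentile 0.89, and -0.35 without shared probe sets). The integrin ITGAV was at 19.8 against 56.5 and ITGA6 at 175 against 357. In RECK, LOX, ITGA6 and ITGAV were also below Zeo, at 141, 93.8 and 39.5, while TNC and COL5A1 were above it, at 870 and 493. YAP targets had 3 of 10 lower, 0 higher and 7 not past 2-fold (-0.18, percentile 2.07, and -0.36 with the floor at the 80th percentile), among them the matricellular gene CCN2, at 1016 against 2707, and CRIM1, at 121 against 291. Focal adhesion genes had 4 of 19 lower, 1 higher and 14 not past 2-fold (-0.07, percentile 2.29, -0.22 when probe sets were averaged and -0.13 after quantile normalisation), with MYL9 at 500 against 1125 and ACTN4 at 4495 against 2019.

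Cholesterol synthesis genes were also lower in RECK/4NQ, with a relative median of -0.32 at percentile 0.31, 1 of 14 members past 2-fold (SC5D, at 28.6 against 80.5), 0 higher and 13 not past 2-fold. Both comparisons share the Zeo array, so the 2 shifts of this list are not separate observations. For RECK over RECK/4NQ its relative median was 0.095 at percentile 81.88. The p53 targets had no member past 2-fold and a relative median of -0.20 at percentile 1.18, which was 0.0024 without shared probe sets and -0.088 with neighbour medians subtracted. MHC class I genes, with none of 9 past 2-fold, had a relative median of -0.29 at percentile 0.32, which was 0.21 without shared probe sets. Notch pathway genes had a relative median of 0.36 at percentile 98.77, which was -0.40 without shared probe sets and 0.018 with the floor at the 60th percentile. Genes of the amino acid response had 0.27 at percentile 97.89, which was 0.12 after quantile normalisation and -0.039 with the floor at the 80th percentile, and NRF2 targets 0.28 at percentile 98.73, the latter with 1 of 17 higher, 0 lower and 16 not past 2-fold and a median of 0.14 with the floor at the 80th percentile. The hypoxia-inducible growth factor gene VEGFA was at 1631 against 669 and the stress gene DDIT4 at 1394 against 579. The N-glycosylation genes, with none of 37 past 2-fold, had a relative median of -0.10 at percentile 1.51 (-0.022 with neighbour medians subtracted).

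In all, 558 genes were higher in RECK/4NQ than in Zeo and 1411 lower. Both signals were measured for 306 and 823, of which 82 and 70 lay over 3 spreads from the median. Other probe sets moved in the same direction in 67.7% of 471 cases and also reached 2-fold in 16.1%. Dimmer probe sets of GATA2 and SC5D moved the opposite way. The share of higher genes was 28.3% as deposited, 45.9% after quantile normalisation (778 higher, 917 lower) and 38.0% after median centring (671 higher, 1094 lower).

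**Figure D1:**
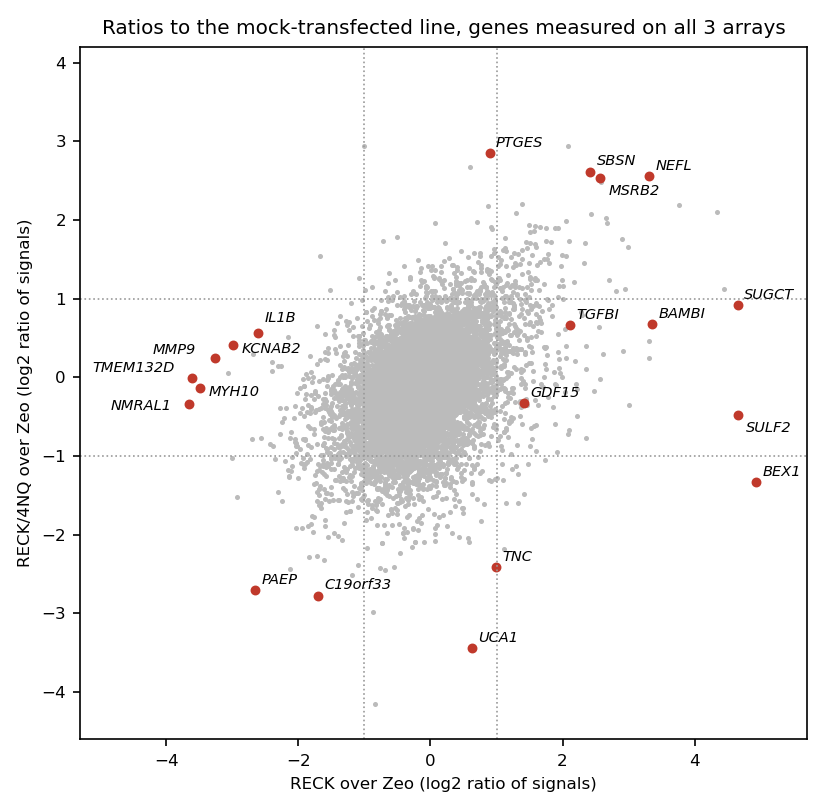
Log2 ratios of signals over Zeo for the 12411 genes measured on all 3 arrays, with RECK on the horizontal axis and RECK/4NQ on the vertical axis; each grey point is a gene, red points are named and dotted lines mark 2-fold. MMP9 and IL1B lie to the left near 0 on the vertical axis (-3.26 and -2.61 for RECK, 0.24 and 0.57 for RECK/4NQ), while UCA1 lies low on the vertical axis (0.62 for RECK, -3.45 for RECK/4NQ).

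Both comparisons use the same Zeo array, which makes their ratios move together without any effect. Across 10802 genes with a mean level at or above the 60th percentile the ratios correlated at 0.377, against 0.50 in data simulated with no effect for the same genes, and their covariance was 0.129 against a simulated 0.131. Of these, genes higher in both numbered 124 (66.55 simulated with no effect, 7.69 for independent lists) and genes lower in both 103 (70.15 simulated, 34.71 for independent lists). Part of this overlap may come from the shared array, which cannot be split. In the simulated data independent lists would share 8.26 higher and 8.38 lower genes, so the downward shift of both transfected arrays was not simulated. The value of 70.15 is therefore not matched to the genes lower in both. SBSN, MSRB2 and NEFL were among the genes higher in both lines, and PAEP, at 90.2 in RECK and 87.2 in RECK/4NQ against 568 in Zeo, among those lower in both.

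The direct comparison of RECK with RECK/4NQ does not involve the Zeo array. It reuses the RECK and RECK/4NQ arrays that were compared with Zeo above. Each gene's log ratio here is the difference between its log ratios to Zeo for RECK and for RECK/4NQ. Differences that appear both here and against Zeo are therefore not separate observations. BEX1 was 77.2-fold higher in RECK (2469 against 32.0), SULF2 35.1-fold, UCA1 16.8-fold (2460 against 146) and SUGCT 13.3-fold. TMEM132D was 12.1-fold lower in RECK, MMP9 11.4-fold, KCNAB2 10.6-fold, MYH10 10.2-fold and IL1B 9.01-fold. The p53, TGF-beta, YAP, focal adhesion and matrix lists were higher in RECK, and the cytokine and unfolded protein lists were lower.

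TNC was 10.6-fold higher in RECK (870 against 82.1) by its brightest probe set, with its others dim. The transcriptional cofactor MN1 was 10.2-fold higher, SLC43A3 9.98-fold, RBPMS2 9.80-fold, the neuronal protein CRMP1 8.74-fold and JMJD8 8.37-fold. HSD17B2 was at least 21.2-fold higher and SOX7 at least 12.3-fold. NMRAL1 was 9.95-fold lower in RECK, the endocytic protein AMPH 9.32-fold, MTMR1 8.69-fold and SEMA6B 7.96-fold. ARMCX2 was at least 15.4-fold lower and GAGE1 at least 9.36-fold. With probe sets averaged, log2 ratios were -2.43 for KCNAB2, 2.52 for SLC43A3 and -1.40 for SEMA6B.

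Of the 17 p53 targets, 6 were higher in RECK than in RECK/4NQ, 0 lower and 11 not past 2-fold, with a relative median of 0.82 at percentile 100. PLK2 was 3.40-fold higher, GDF15 3.35-fold, GADD45A, a growth arrest gene, 2.98-fold (563 against 189) and the p53 ubiquitin ligase MDM2 2.09-fold. TGF-beta targets had 3 of 15 higher, 0 lower and 12 not past 2-fold (0.54, percentile 100, and 0.20 when probe sets were averaged). YAP targets had 3 of 10 higher, 1 lower and 6 not past 2-fold (0.44, percentile 99.83, and 0.71 with the floor at the 80th percentile), with CCN2 at 2376 against 1016 and LATS2 at 98.4 against 221. Focal adhesion genes had 5 of 19 higher, 0 lower and 14 not past 2-fold (0.30, percentile 99.95), with MYL9 5.27-fold higher and the caveolin gene CAV2 2.59-fold higher. Matrix genes had 6 of 40 higher, 1 lower and 33 not past 2-fold (0.27, percentile 99.94, and 0.17 without shared probe sets), with COL5A1 5.36-fold higher.

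Cytokines and NF-kB targets had 3 of 26 lower, 2 higher and 21 not past 2-fold (-0.40, percentile 0.36), with CCL5 3.46-fold lower. CXCL2 was 2.27-fold higher by its brightest probe set, while another read 10.03 against 25.95. Unfolded protein response genes had 2 of 29 lower, 1 higher and 26 not past 2-fold (-0.33, percentile 0.56). The stress protein gene HERPUD1 was at 1225 against 2542 and the secreted chaperone gene MANF at 1324 against 2673, while ATF3 was 5.97-fold higher by its brightest probe set, and its others read 140 against 69.3 and 49.6 against 60.9. Amino acid response genes had 2 of 18 lower, 0 higher and 16 not past 2-fold (-0.40, percentile 0.67), with DDIT4 at 275 against 1394. Hypoxia and glycolysis genes had 3 of 25 lower, 0 higher and 22 not past 2-fold (-0.32, percentile 0.67), with the glucose transporter SLC2A3 at 155 against 435. Without shared probe sets these medians came to -0.017 and -0.016. Fatty acid synthesis genes had 1 of 9 lower, 0 higher and 8 not past 2-fold (-0.46, percentile 1.42, and -0.033 when probe sets were averaged), with the carboxylase ACACA at 216 against 463.

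Markers of blood cells, a check for other cell types, had 3 of 10 members lower, 0 higher and 7 not past 2-fold, with a relative median of -1.01 at percentile 0.04 over 6 members. With the floor at the 60th percentile the median was -0.15, at the 20th -0.32, and with probe sets averaged -0.37. These signals were weak, with CD74 at 25.8 in RECK and 88.4 in RECK/4NQ and ITGAM at 12.2 and 42.7. Cell cycle genes, with 0 of 38 higher, 1 lower and 37 not past 2-fold, had a relative median of -0.0022 at percentile 83.77. In the comparisons with Zeo it was -0.019 at percentile 31.41 for RECK and 0.10 at percentile 56.02 for RECK/4NQ.

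In all, 1141 genes were higher in RECK than in RECK/4NQ and 886 lower, 684 and 561 of them measured on both arrays, and 176 and 84 of these over 3 spreads from the median. Other probe sets moved in the same direction in 73.6% of 655 cases and also reached 2-fold in 22.7%. Probe sets of MDM2, LATS2, GDF15 and ITGAM other than the brightest moved the opposite way. The share of higher genes was 56.3% as deposited and 63.8% after median centring (1370 higher, 778 lower) and 56.8% after quantile normalisation, but 47.6% with the floor at the 80th percentile (167 higher, 184 lower).

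**Figure D2:**
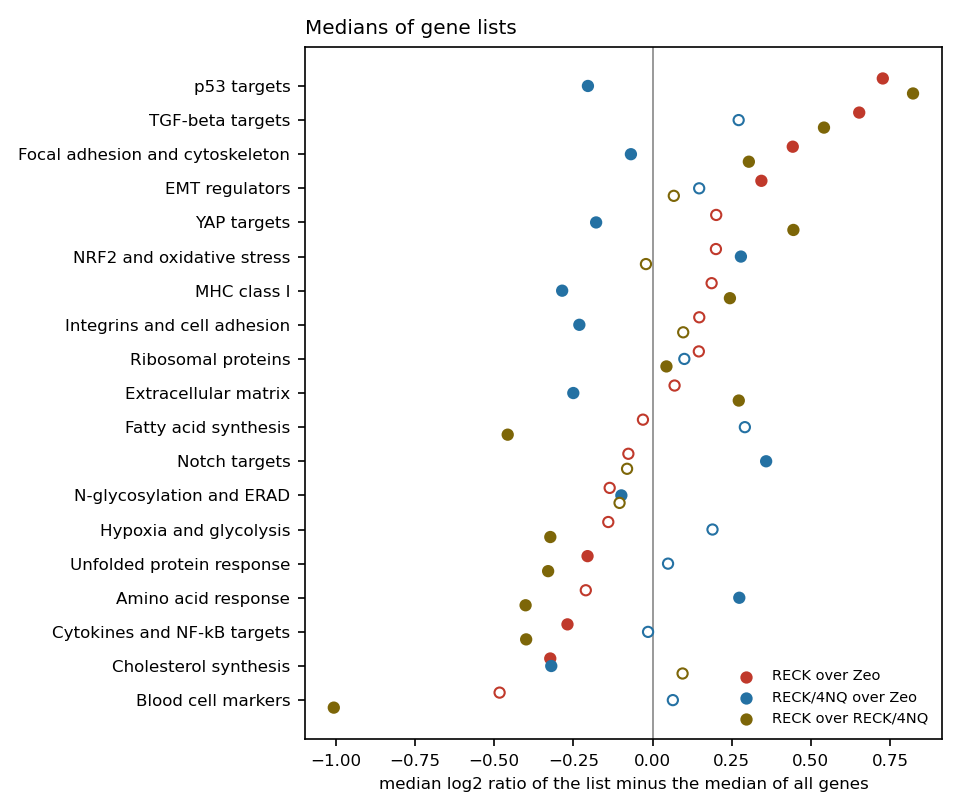
Median log2 ratio of each list minus the median of all genes, for the 19 lists that lay outside the middle 95% of random lists in at least 1 comparison; filled points lie outside that range and open points inside. The line at 0 is the median of all genes, not of genes of the same level. The p53 targets lie at 0.73 for RECK over Zeo, 0.82 for RECK over RECK/4NQ and -0.20 for RECK/4NQ over Zeo.

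Genes at which 1 array stood apart from the other pair numbered 329 for RECK (113 higher, 216 lower), 264 for RECK/4NQ (52 higher, 212 lower) and 229 for Zeo (140 higher, 89 lower), of 12411 genes. The RECK array was also the one with brighter hybridisation controls, by a log2 ratio of 0.38 over Zeo and 0.37 over RECK/4NQ. Among the 10802 genes with a mean level at or above the 60th percentile the counts were 281, 209 and 149, against 123.7, 122.7 and 121.1 in data simulated with no effect. Among genes with all signals above the 80th percentile the counts were 87, 34 and 17 of 5901. RECK stood apart with SULF2, JMJD8, ADAMTS2, a procollagen peptidase, MN1 and FBXL16 higher, and with MMP9, NMRAL1, TMEM132D, MYH10 and MTMR1 lower. RECK/4NQ stood apart with SLPI, a secreted protease inhibitor, NUP58 and CYP4V2 higher, at 3.27-fold, 2.82-fold and 3.91-fold above Zeo by the brightest probe sets (others read 28.0 against 34.8 for NUP58 and 19.02 against 25.64 for CYP4V2), and with GATA2, a haematopoietic transcription factor, the adaptor GRB7 and HSPG2, the basement membrane proteoglycan perlecan, lower, at 3.96-fold, 4.23-fold and 4.09-fold below Zeo. Zeo stood apart with PAEP, DEFB124 and ABCB5 higher than in both transfected lines and with SBSN, MSRB2 and the vesicle protein gene VAMP8 lower.

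**Figure D3:**
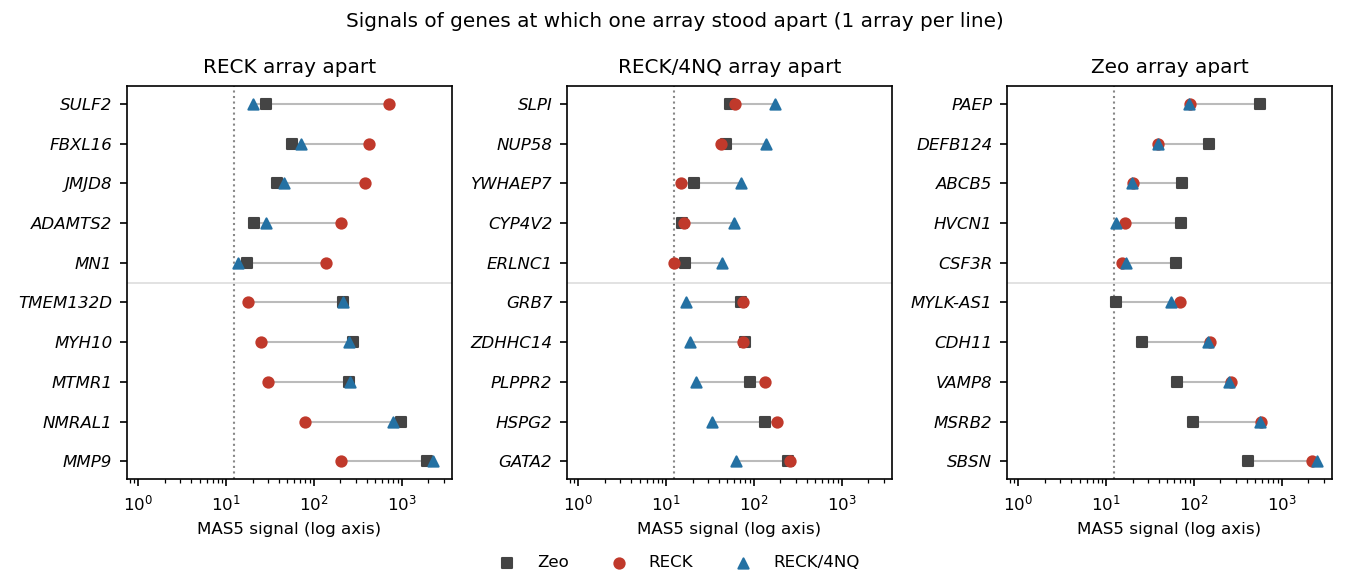
MAS5 signals on a log axis of genes at which the RECK, RECK/4NQ or Zeo array stood apart, 5 higher and 5 lower per array; squares are Zeo, circles RECK and triangles RECK/4NQ, 1 array each, and the dotted line is the floor of 12.2. MMP9 lies at 203 in RECK and at 1947 and 2306 in Zeo and RECK/4NQ, and SULF2 at 714 against 28.4 and 20.4.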

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

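The tests of all 3 explanations of the RECK array's counts below were chosen after the result was seen. The probe sets that the platform's annotation does not list with a gene were not used in the comparisons. Of these 11721 probe sets, 365 were higher and 715 lower in RECK than in Zeo, and 345 were higher and 648 lower in RECK/4NQ. Among those measured on both arrays with a mean level above the 60th percentile, the largest ratio was 5.34-fold for RECK, at probe set 213981_at with a signal of 88.3 against 16.6, and 5.95-fold for RECK/4NQ, at probe set 223632_s_at with a signal of 76.6 in place of 12.9.

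The RECK array stood apart from the other pair more often than the RECK/4NQ or the Zeo array, at 329, 264 and 229 genes. If noise of dim probe sets were the reason, the excess would shrink among bright genes, but with the floor at the 80th percentile the RECK count was 2.56 times the larger of the other counts. An offset of the whole RECK array would be removed by median centring, after which the ratio was 1.31 (331, 253 and 203 genes for RECK, RECK/4NQ and Zeo). With neighbour medians subtracted and the floor at the 80th percentile the ratio was 2.73 (71, 26 and 11 genes), so the RECK count stayed the largest. All 3 counts were lower than the 87, 34 and 17 without this subtraction, and part of each may go with regional shifts. Shifts of blocks shorter than the neighbourhood are not removed this way, so a regional part is not excluded. The hybridisation controls of the RECK array also stood apart, at log2 ratios of 0.38 over Zeo and 0.37 over RECK/4NQ, against 0.0092 for RECK/4NQ over Zeo. Whether a difference in the handling of this array adds to its count was not tested. That, an effect of RECK with its glycosylation sites, and a chance difference of this line from the other lines all stay open, since each construct was measured in 1 line on 1 array.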

How the results depend on the processing

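The floor at the 80th percentile and the subtraction of neighbour medians were chosen after seeing the data, the other alternatives before. For genes higher and lower in RECK than in Zeo, higher and lower in RECK/4NQ than in Zeo, and higher and lower in RECK than in RECK/4NQ, a floor at the 20th percentile gave 1697, 2440, 1415, 2686, 2318 and 1888, the 60th percentile 328, 526, 167, 456, 469 and 382, the 80th percentile 109, 172, 52, 93, 167 and 184, and a 3-fold threshold 234, 329, 121, 289, 329 and 193. For genes at which RECK, RECK/4NQ and Zeo stood apart these settings gave 731, 691 and 593, then 170, 95 and 69, then 87, 34 and 17, and with 3-fold 71, 34 and 31. A higher floor or threshold leaves fewer genes to call by its construction, and a higher floor shrinks ratios with 1 weak side. Quantile normalisation gave 917 genes lower in RECK/4NQ than in Zeo in place of 1411. The other 44 of 81 recomputed counts were within 1.5 times their value as reported. Of the 2124 genes called in RECK against Zeo, 1713 were kept in the same direction after quantile normalisation and 1890 after neighbour medians were subtracted.

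Of 247 recomputed list medians, 207 moved by less than their own spread, 33 moved further and 7 changed sign. Without shared probe sets the medians for RECK/4NQ over Zeo were -0.40 for Notch targets, 0.21 for MHC class I and 0.0024 for p53 targets, and MHC class I came to -0.0082 for RECK over RECK/4NQ. With the floor at the 80th percentile Notch targets came to -0.035 and the amino acid response to -0.039 for RECK/4NQ over Zeo. With neighbour medians subtracted the ribosomal proteins came to -0.0067 for RECK over RECK/4NQ. Of 601 recomputed ratios of named genes, 85 moved beyond their spread, of which 64 had 1 array below the floor, so that the value is only a bound. Of the ratios past 2-fold 3 changed sign: with probe sets averaged, AK5 came to -0.37 for RECK/4NQ over Zeo and DLL1 to 0.19 for RECK over Zeo, and without shared probe sets CDH11 came to a bound of -1.70 for RECK/4NQ over Zeo. Of smaller ratios 7 changed sign, among them RECK over Zeo at -0.16 with probe sets averaged and -0.047 without shared ones. Probe sets were averaged before the floor was applied. For AK5 in RECK/4NQ, DLL1 in Zeo and RECK in the RECK line, signals of 3.08, 2.97 and 2.08 pulled the averages toward the changed sign. Averages with the floor applied first were not made, so these changes may come from signals below the floor. The cause of the other changes of sign was not tested. Weak signal limits what can be seen: the median robust spread of log2 ratios between RECK and Zeo was 0.69 for genes between signals of 12.2 and 27.8 and 0.27 above 2000.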

Other observations

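Tests of the regional pattern and of probe choice and dim probe sets for the p53 list were chosen after the result was seen; the second p53 list and its prediction were written before its values were looked at. Some gene groups fixed in advance were not described above. Homeobox genes went both ways in RECK against Zeo, with 3 of 23 members higher, 4 lower and 16 not past 2-fold. HOXD10 was at 74.1 against 12.7 and MSX2 at 139 against 59.4, while MSX1 was at 326 against 991, HOXB2 at 787 against 1953 and HOXD4 at 17.0 against 46.9 by its brightest probe set, where another read 29.3 against 20.4. NRF2 targets had 4 of 17 higher in RECK, 1 lower and 12 not past 2-fold, and the 4 included the aldo-keto reductases AKR1C3, at 93.2 against 18.6, and AKR1B10, at 139 against 34.0, while GCLC, the rate-limiting enzyme of glutathione synthesis, was at 38.1 against 81.0.

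Among growth factor genes, the ligand NRG1 was at 253 in RECK against 66.1 in Zeo, the receptor gene PDGFRB at 67.3 against 22.9, and GAS6, the ligand of the AXL receptor, at 1085 against 2611. The Wnt inhibitor gene DKK3 was at 1105 in RECK, 498 in Zeo and 164 in RECK/4NQ. The interferon-induced gene IFITM1 was at 562 in RECK, 1033 in Zeo and 2290 in RECK/4NQ, and the cancer-testis antigen MAGEC2 at 772, 307 and 101. Dimmer probe sets of NRG1, GCLC and MAGEC2 did not all follow these directions. Of 19 ribosomal protein genes and 13 housekeeping genes none passed 2-fold in any comparison.

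Some runs of genes that neighbour each other in the genome shifted together, while the correlation between neighbours was only 0.10 for RECK over Zeo. In windows of 40 neighbouring genes, those from GPR107 to PAEP were lower in RECK than in Zeo by a relative median of -0.72, with 35 of 40 genes on that side, and those from RCC1 to ZNF362 higher by 0.51. The first window was also lower in RECK/4NQ than in Zeo, at -0.40, and was at -0.22 for RECK over RECK/4NQ. The second was at 0.15 and 0.43 in these comparisons. Windows began every 10 genes and so overlapped. A chance order of genes was tested with 1000 shuffles, and 22 of 865 windows lay beyond all of them; after trends with signal level and gene density were removed, 20 windows still did. For RECK/4NQ over Zeo and RECK over RECK/4NQ, 12 and 7 windows did as measured, and 8 and 12 after the trends were removed. A difference in copy number between the lines would move whole blocks. The spread of ratios within the 6 extreme windows was at a median of 1.02 times that of all genes (range 0.828 to 1.36). These windows were chosen for extreme medians, which a few strongly changed genes cannot give, so this spread cannot decide the question. A regional difference in transcription could also move whole blocks, and no DNA was analysed here.

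The p53 targets were higher in RECK than in Zeo. The choice of probe set was tested by averaging all probe sets, which gave a relative median of 0.65, and by leaving out shared ones, which gave 0.86; with the floor at the 80th percentile, against noise of dim probe sets, 12 members had a median of 0.73. Higher p53 activity in the RECK line, as a hypothesis, predicts that other p53 targets are higher too: a second list of 43 measured targets with no member in common had a relative median of 0.29, at percentile 99.96, with 29 of 43 above the median of all genes, and 0.40 at percentile 100 for RECK over RECK/4NQ. The latter shares the RECK array and is not separate support, since the list lay lower in RECK/4NQ than in Zeo, at -0.14, percentile 1.98. In the second list RPS27L was at 6710 against 3653 and AEN at 964 against 613, while ZNF79 was at 72.3 against 136. Whether this goes with RECK or with this line's own history was not tested, since there is 1 line per construct.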
